A study of Arabidopsis thaliana with 12 samples.

How the data were processed

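The data are 12 single-colour oligonucleotide arrays, each hybridised with biotin-labelled total RNA from mature rosette leaves of Arabidopsis thaliana. Sample titles and characteristics place 3 arrays in each of 4 groups: the accession Ws-2 and the line ape2, each in a condition called L and a condition called H in the titles. The titles do not say what L and H stand for, and they are used here as names only. The deposited values are linear signal intensities, 1 per probe set and array, made by the authors with MAS5 per the submitters' processing notes. The MAS5 version, the scanner settings and the detection calls are not given in the sources used here. The values themselves show that the 2% trimmed mean of each array had been brought to 100 before deposit, so a change shared by most transcripts on an array would not be visible. MAS5 summarises each array by itself, with a correction for mismatch probes that makes dim signals noisy, and probe sets that match related transcripts report their sum.

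The array table holds 22810 probe sets, of which 64 are controls. The platform annotation used here names 1 gene for 13513 probe sets and several for 503, while 8730 have no gene named in it. Of the probe sets with 1 gene, 13436 were matched to a RefSeq gene table, 11885 of them by locus code only and 1551 with a gene symbol, and 77 kept the annotation's name. No gene was named from a probe set with several genes.

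Control probe sets were left out and each array was rescaled to a trimmed mean of 100. Values were analysed as log2(signal + 10), so a fold change understates the change of a dim transcript and its size depends on the offset. A gene is called dim here when its mean signal is under 20 in a group compared. Probe sets with a signal of 20 or more on at least 3 of the 12 arrays were kept, which left 16076 for testing and removed 6670. A linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with a prior variance that follows the mean intensity and is robust to outlying genes. The 7 contrasts were ape2 minus Ws-2 in each condition, H minus L in each genotype, the interaction, and the means of the genotype and the condition contrasts. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, and an adjusted p under 0.05 is called here. Unless a test is named, an adjusted p in the text is from this model. Nothing in the labels says that replicates came from separate plants or pots, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision, and the standard error of a change ranges with the brightness of the transcript.

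Gene lists were tested with camera in limma with a preset correlation between genes of 0.01, for lists with at least 5 measured genes, and the p-values were adjusted over the lists within a contrast. The 44 lists fixed at the start hold 620 genes, of which 108 have a probe set named here, so 7 of them could be tested. Further lists, which extend the fixed ones, hold the genes of the organelle genomes or gather genes by the stem of their symbol, were drawn up after reading the annotation and before any contrast was fitted, and 41 of them could be tested. Each list was tested again with a correlation estimated from the residuals. No camera call in any of the 7 contrasts was kept with that estimate. Its adjusted p is printed with each called list described before the results flagged for a closer look. The fry test asks whether the genes of a list move on balance in a single direction and does not compare them with other genes.

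The groups, contrasts, tests, the 44 lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes TPT, the 10 largest rises and 10 largest falls among called probe sets with 1 gene and groups that do not overlap, up to 4 called members of each list that passed camera or held at least 2 called genes, the 10 smallest p-values where fewer than 5 genes were called, and the measured plastid envelope translocators. Because many of these calls depended on single arrays, a further choice was made after the values were seen. Full values are given mainly for genes whose call was kept in every alternative and whose change stayed within 1.5 times without each array, which were 26 of 41 called named genes for ape2 in condition L, 30 of 41 in condition H, 12 of 25 for H in Ws-2 and 13 of 24 for H in ape2. Called members of the lists, and genes that the rule named in another contrast, are also given and were chosen after their values were seen.

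The alternatives were offsets of 1 and 32, no filter and a filter at 50, quantile normalization, no rescaling, a constant prior, array weights, only the groups compared, the replicate number as a block, fry, an estimated correlation, and leaving out each array in turn. A fit without the 3 arrays highest on the leading component of variation within groups was added after seeing the data. The model was tested on simulated data with the mean and spread of the real arrays. The simulated noise was drawn separately for each probe set and array, without variation shared by arrays. In the real data the leading component within groups held 25.6% of that variance, so recovery and false calls may differ there. For ape2 against Ws-2 in condition L, with 16076 probe sets, it recovered 33 of 67 probe sets changed by 0.5 on the log2 scale, 60 of 67 changed by 1 and 66 of 66 changed by 2, and called 7 unchanged probe sets.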

Results

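Transcripts were measured in unshaded, mature rosette leaves of Arabidopsis at developmental stage 3.7. Ws-2 is a natural accession used as the wild type, and ape2 is a T-DNA insertion line in the Ws-2 background. The series concerns a mutant of TPT, the triose phosphate/phosphate translocator of the inner chloroplast envelope, which exports the products of photosynthetic carbon fixation to the cytosol in exchange for phosphate. Each genotype was sampled in condition L and in condition H, with 3 arrays per group. The median signal of an array lay between 36.2 and 40.1, and between 63.7% and 67.7% of its probe sets reached a signal of 20. The correlation of log2 signals between arrays of different groups ran from 0.953 to 0.981 and overlapped with that within groups, from 0.975 to 0.985. The leading principal component held 30.9% of the variance and the next held 15.4%. The ratio of the 3' to the 5' probe set of actin, a sign of RNA integrity, ranged from 2.22 to 3.24 over the arrays, with means of 2.98 ± 0.23 in Ws-2 L, 2.63 ± 0.36 in Ws-2 H, 2.73 ± 0.21 in ape2 L and 2.41 ± 0.12 in ape2 H (SD, n = 3). For GAPDH the means in the same order were 2.05 ± 0.22, 1.86 ± 0.26, 1.87 ± 0.20 and 1.77 ± 0.05. Both ratios had lower means in H than in L in each genotype, with overlapping ranges.

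**Figure D1:**
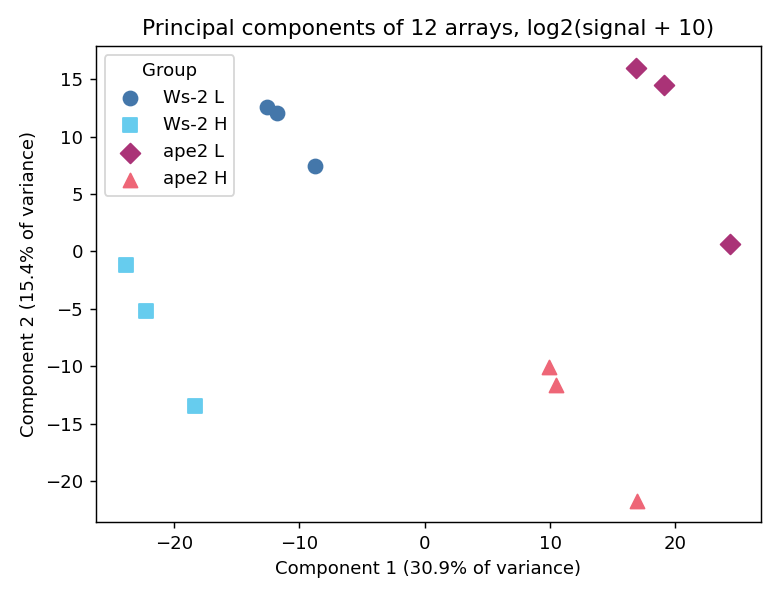
Principal components of the 12 arrays, computed from log2(signal + 10) of the tested probe sets. Each point is an array, coloured by group, and the axes give each component's score and its share of the variance, 30.9% for the leading component and 15.4% for the next.

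No probe set is named for TPT in the annotation used here, so its transcript could not be followed by name and the genotype labels were not checked on it. XPT (AT5G17630), which exchanges xylulose 5-phosphate and is the only plastid envelope translocator of the list measured here, differed by 0.03 ± 0.08 on the log2 scale between ape2 and Ws-2 in condition L (adjusted p = 0.889) and by -0.20 ± 0.08 in condition H (0.134). Among all tested probe sets the largest change between the genotypes was that of 248886_at, which has no gene named here and was chosen after its values were seen. Its signal fell from 4046 ± 427 in Ws-2 L to 174 ± 4.48 in ape2 L, a log2 change of -4.46 ± 0.09 (SE, adjusted p = 1.77e-14), and from 3965 ± 435 in Ws-2 H to 172 ± 7.88 in ape2 H, a change of -4.44 ± 0.09 (1.88e-14).

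The comparison of ape2 with Ws-2 in condition L asks how leaf transcripts differ in the translocator mutant. CSLA01, a cellulose synthase-like gene, fell from a signal of 236 ± 55.8 to 41.3 ± 9.97 (SD, n = 3), a log2 change of -2.25 ± 0.19 (SE, adjusted p = 1.27e-05). JMT, whose product methylates jasmonic acid, fell from 149 ± 4.43 to 44.7 ± 4.61, by -1.54 ± 0.11 (3.46e-07). APL3, a large subunit of ADP-glucose pyrophosphorylase in starch synthesis, fell from 90.2 ± 11.7 to 47.3 ± 2.75 (-0.80 ± 0.11, adjusted p = 1.72e-04). AKINBETA1, a regulatory subunit of the energy-sensing kinase SnRK1, rose from 35.5 ± 2.37 to 72.4 ± 8.15 (0.85 ± 0.11, adjusted p = 1.96e-04). ATG8E, a ubiquitin-like protein of autophagosomes, rose from 33.6 ± 3.05 to 94.96 ± 6.45 (1.27 ± 0.12, adjusted p = 6.34e-06).

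On an extended list drawn up after reading the annotation, genes repressed by sugar or induced by carbon starvation were higher in ape2 in condition L. Of the fixed list of such genes 5 have a probe set named here, and camera called 0 of the 7 fixed lists in this contrast. Of the 15 measured genes of the extended list, 4 rose and 0 fell over all genes tested by limma, with 7 higher and 1 lower when adjusted over the list alone. The median log2 change of the list was 0.38 and its mean 0.37 (camera adjusted p = 0.00777, and adjusted p = 0.333 with an estimated correlation). Its risers were AT5G19120, which is dim (1.80 ± 0.20), AKINBETA1, AT3G26510 (0.42) and AT3G15450 (0.40). The call of AT3G26510 was lost without Ws-2 L 2, Ws-2 L 3, ape2 L 1 or ape2 L 2 (adjusted p up to 0.0959), and that of AT3G15450 without any array except ape2 L 1 and ape2 H 2 (up to 0.166). Members for the breakdown of branched-chain amino acids lay near 0, with IVD at -0.03, ETFQO at 0.04, MCCA at 0.04 and MCCB at -0.04. In the family of autophagy genes with ATG symbols, all 8 measured members had positive changes and 2 rose, ATG8E and ATG8F (0.45 ± 0.09, adjusted p = 0.00612). The family's mean was 0.31 (camera adjusted p = 0.0197, and adjusted p = 0.507 with an estimated correlation), a call lost without the 3 arrays highest on the leading within-group component.

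Among genes of starch and sugar handling, 2 of 9 measured on the extended starch list fell in condition L and 0 rose in the limma test. They were APL3 and its relative APL4, which is dim, at -0.61 (adjusted p = 0.0438), whose call was lost with an offset of 1 (0.0504) and without any array except Ws-2 H 3 and ape2 L 1 (up to 0.183). SWEET17, a fructose transporter of the vacuole, was the only one of the 9 measured genes on the list of sugar transporters and invertases to pass the test, at -0.79 ± 0.15 (0.0045, and 1 lower when adjusted over the list alone). SAG29, a SWEET sugar transporter also known as SWEET15 that stands on the senescence list, fell by -1.10 ± 0.23 (0.00718) from a signal of 22.1 ± 2.83 to 5.23 ± 3.31, which is close to background, so that the size depends on the offset, with -2.08 at an offset of 1 and -0.54 at 32. Of 6 measured genes of flavonoid synthesis on the extended list, 3 fell, and all 3 attach sugars to flavonols. UGT78D1 and AT1G06000, both rhamnosyltransferases, were at -0.74 ± 0.15 (0.00414) and -0.69 ± 0.14 (0.00485), and UGT78D2 at -0.37 (0.0166) lost its call without Ws-2 L 1, Ws-2 L 3, ape2 L 2 or ape2 L 3 (up to 0.0721). UGT74B1, a glucosyltransferase of glucosinolate synthesis, fell by -0.81 ± 0.12 (4.15e-04).

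In chlorophyll synthesis, PORB rose by 0.36 ± 0.07 (adjusted p = 0.00373), and 2 of 6 measured members rose over all genes and 2 adjusted over the list alone. The other was CHLI2, at 0.43 (0.0301), whose call was lost without Ws-2 L 1, Ws-2 L 2, Ws-2 L 3, ape2 L 1 or ape2 L 3 (up to 0.124), and the list's camera adjusted p was 0.182. CCL, a clock-associated gene, rose by 1.05 ± 0.11 (1.9e-05), and GIGANTEA (GI), an evening clock gene, was at -0.35 (0.014), a call that was lost without Ws-2 L 1 (0.0567). The jasmonate-responsive defensin PDF1.2 gave 1.52 ± 0.14 (7.95e-06), which is uncertain because its near-identical copy PDF1.2b can hybridise to the same probes. In the family of RALFL signal peptides all 6 measured members had negative changes, with 4 lower when adjusted over the list alone, and 1 fell over all genes, RALFL34 at -0.34 (0.0243), whose call was lost without Ws-2 L 2, Ws-2 L 3, ape2 L 1 or ape2 L 2 (up to 0.11). The family's mean was -0.36 (camera adjusted p = 0.00741, and adjusted p = 0.333 with an estimated correlation), a call lost with no filter. Of 105 measured cytosolic ribosomal proteins, 10 rose, among them AT3G13580 (0.52, 0.00742), and 1 fell. Their mean of 0.10 passed camera (0.00263, and adjusted p = 0.818 with an estimated correlation) and was lost without ape2 L 3, where the mean was 0.04 (adjusted p = 0.551). For the 5 nuclear photosystem and electron transport subunits, the 8 plastid thioredoxin and NADP redox genes and RCA, PRK and SBPASE of the Calvin-Benson cycle, limma called 0 genes in either genotype contrast. The 4 measured photorespiration genes were all lower in condition L when adjusted over the list alone, with HPR at -0.19, AT1G11860 at -0.16 and AT1G80380 at -0.20, while limma called 0 of the 4 over all genes. In the mean over both conditions 2 of the 4 fell over all genes and 3 were lower when adjusted over the list alone. The 2 were AT1G80380 at -0.18 (0.0189), lost without ape2 L 1 (0.0508), and AT1G11860 at -0.15 (0.0235), lost without ape2 L 2 or ape2 H 2 (up to 0.0577). Among 7 antioxidant enzymes, GR alone passed in condition L at -0.25 (0.0242), and its call was lost without Ws-2 L 1, Ws-2 L 3, ape2 L 1 or ape2 L 3 (up to 0.0915). The measured markers of other cells, FMA of guard cells, EXPA7 of root hairs and AUR1 of dividing cells, were at 0.08, 0.04 and 0.09 (0.788, 0.946 and 0.684).

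The 13 measured plastid-encoded transcripts of the fixed list did not pass as a list in condition L, with a mean of -0.11 (camera adjusted p = 0.182) and 0 genes called by limma. On the added list of the 69 measured genes of the plastid genome 55 had negative changes, with a mean of -0.10 (camera adjusted p = 5.52e-04, and adjusted p = 0.761 with an estimated correlation). The mean was -0.05 without ape2 L 1 and -0.15 without Ws-2 L 1, and the call was lost with quantile normalization and with fry. By limma 4 fell and 2 rose over all genes, with 6 and 3 when adjusted over the list alone. The gene rps16 of the plastid ribosome fell by -0.63 ± 0.11 (0.00205), and the others called were atpF (-0.34), psbT (-0.32), cemA (-0.28), petD (0.74) and psbE (0.41). Photosystem genes of the plastid had a mean of -0.14 (camera adjusted p = 0.00777, and adjusted p = 0.731 with an estimated correlation), and ribosome and RNA polymerase genes a mean of -0.08 (camera adjusted p = 0.0234, and adjusted p = 0.731 with an estimated correlation). Both calls were lost without Ws-2 L 3 or ape2 L 1 (up to 0.113 and 0.16), and without ape2 L 1 the means were -0.09 and -0.04. The call of atpF was lost without Ws-2 L 3 or ape2 L 1 (up to 0.0755), that of psbT without Ws-2 L 2 (0.0532), that of petD without Ws-2 L 1, Ws-2 L 3, ape2 L 1, ape2 L 2, ape2 L 3 or ape2 H 1 (up to 0.117), that of psbE without Ws-2 L 1, Ws-2 L 3, ape2 L 2 or ape2 L 3 (up to 0.145) and that of cemA without Ws-2 L 2, Ws-2 L 3, ape2 L 1 or ape2 L 3 (up to 0.146).

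Over all genes, limma called 1575 probe sets in condition L, 810 higher and 765 lower in ape2, with 79 of the rises and 27 of the falls at least 2-fold. Of the 746 called probe sets with 1 gene named, 396 were higher and 350 lower. The largest named rises, chosen by the fixed rule, included AT3G62550, from a signal of 90.4 ± 15.5 to 389.8 ± 44.7, AT3G06070 (1.82 ± 0.13), AT5G47455, which is dim in Ws-2 (1.69 ± 0.38), AT5G24210 (1.58 ± 0.31), AT5G48490 (1.48 ± 0.19), AT4G17610, which is also dim (1.48 ± 0.24), and AT1G55960 (1.34 ± 0.09), with adjusted p from 1.28e-07 to 0.0107. The largest falls included AT1G78020 (-1.51 ± 0.07), AT3G14200 (-1.44 ± 0.13), TBL26 (-1.34 ± 0.07), AT2G27420 (-1.28 ± 0.08), AT4G27652 (-1.21 ± 0.14) and AT1G22160 (-1.07 ± 0.12), with adjusted p from 3.6e-09 to 6.13e-05. The 3 arrays of each genotype did not overlap for 1558 of the called probe sets and for 26.5% of all tested, where chance gives 10%. Without Ws-2 L 2 the count of calls was 1024, and without Ws-2 L 3 it was 1046.

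**Figure D2:**
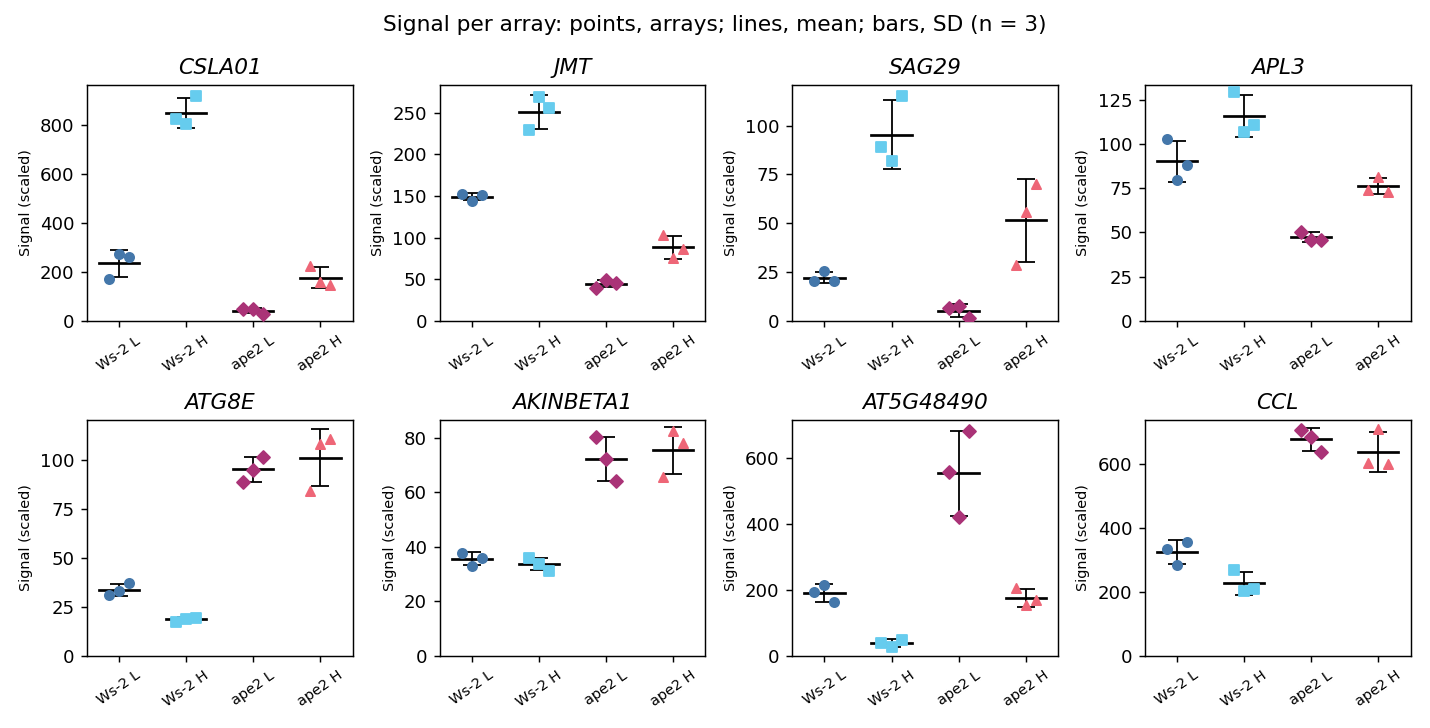
Signal per array (linear axis from 0) of 8 named genes, with 1 point per array and bars for the group mean and SD (n = 3 per group). CSLA01 is lowest in ape2 L, at 41.3, and highest in Ws-2 H, at 850, while ATG8E is at 94.96 and 100.9 in ape2 L and ape2 H against 33.6 and 18.5 in Ws-2 L and Ws-2 H.

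The same genotype comparison in condition H gave ATG8E, AKINBETA1, CSLA01 and JMT in the same directions. ATG8E rose from a signal of 18.5 ± 1.04 in Ws-2 to 100.9 ± 14.5 in ape2 (SD, n = 3), a log2 change of 1.95 ± 0.12 (SE, adjusted p = 4.73e-08) whose size depends on the offset, with 2.38 at 1 and 1.39 at 32, and AKINBETA1 rose from 33.6 ± 2.31 to 75.4 ± 8.64 (0.97 ± 0.11, 3.99e-05). CSLA01 fell from 850 ± 62.1 to 176 ± 42.4 (-2.23 ± 0.19, adjusted p = 8.19e-06) and JMT from 251 ± 20.6 to 88.3 ± 13.8 (-1.42 ± 0.11, 4.81e-07). CCL rose from 226 ± 37.1 to 637 ± 62.4 (1.46 ± 0.11, adjusted p = 4.49e-07).

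Of the 15 sugar-repressed and starvation genes on the extended list, 4 rose in condition H and 0 fell by limma, with 4 and 0 when adjusted over the list alone, and 14 of the 15 changes were positive. Beside AKINBETA1 the risers were AT5G19120, which is dim (1.44 ± 0.20, with 2.75 at an offset of 1 and 0.71 at 32), AT3G26510 (1.29 ± 0.11, adjusted p = 2.1e-06) and AILP1 (1.06 ± 0.20, 0.00529). The list's median was 0.26 and its mean 0.43 (camera adjusted p = 1.23e-04, and adjusted p = 0.275 with an estimated correlation). The ATG family had a mean of 0.50 (camera adjusted p = 1.23e-04, and adjusted p = 0.275 with an estimated correlation), with ATG8F at 0.67 ± 0.09 (1.93e-04). ATG8H passed at 0.50 (0.0479) and lost its call without Ws-2 L 2, Ws-2 H 1, Ws-2 H 2, Ws-2 H 3, ape2 L 1, ape2 L 3, ape2 H 1 or ape2 H 2 (up to 0.169). In the RALFL family 5 of 6 changes were negative and 3 fell over all genes, with 3 when adjusted over the list alone. RALFL22 fell by -0.63 ± 0.09 (1.76e-04), RALFL34 at -0.35 (0.0194) lost its call without Ws-2 H 2, Ws-2 H 3, ape2 H 2 or ape2 H 3 (up to 0.0875), and RALFL32 at -0.61 (0.0219) without Ws-2 H 2, Ws-2 H 3, ape2 H 1 or ape2 H 2 (up to 0.104). The family's mean was -0.37 (camera adjusted p = 0.0213, and adjusted p = 0.377 with an estimated correlation).

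The 3 flavonol glycosyltransferase genes called in condition L were also lower in ape2 in condition H. AT1G06000 was at -1.05 ± 0.14 (adjusted p = 1.25e-04), UGT78D1 at -0.84 ± 0.15 (0.00135) and UGT78D2 at -0.70 ± 0.09 (9.31e-05). They are 3 of the 6 measured flavonoid genes on the extended list, of which 0 rose by limma and whose camera adjusted p was 0.102. UGT74B1 was at -0.71 ± 0.12 (9.79e-04), APL3 at -0.54 ± 0.11 (0.0032) and PORB at 0.45 ± 0.07 (4.91e-04). GH9C2, an endoglucanase of the cell wall, fell by -0.74 ± 0.09 (3.49e-05), and had fallen by -0.65 ± 0.09 in condition L (1.77e-04). SAG29 was at -0.83 (0.0337) and lost its call without Ws-2 H 1, Ws-2 H 3, ape2 H 1 or ape2 H 2 (up to 0.148). Among plastid-encoded transcripts, rbcL, the large subunit of Rubisco, rose from 1547 ± 159 to 2817 ± 367 (0.86 ± 0.11, adjusted p = 6.41e-05). The ribosomal protein gene rps14 rose by 2.21 ± 0.39 (0.00747), petD of the cytochrome b6f complex by 1.33 ± 0.20 (8.3e-04) and psbE of photosystem II by 0.54 ± 0.11 (0.00632). Of the 13 measured plastid-encoded genes on the fixed list 3 rose, rbcL, rpoB (0.63) and psbA (0.28), and 3 when adjusted over the list alone, with a camera adjusted p of 0.255. The call of rpoB was lost without Ws-2 L 1, Ws-2 H 1, Ws-2 H 3, ape2 L 3, ape2 H 1 or ape2 H 3 (up to 0.126), and that of psbA without Ws-2 L 2, Ws-2 H 2, Ws-2 H 3, ape2 L 1, ape2 L 3, ape2 H 1 or ape2 H 3 (up to 0.18).

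In condition H limma called 1690 probe sets, 800 higher and 890 lower in ape2, of which 112 rises and 44 falls were at least 2-fold. The largest named rises included AT1G19960 (2.25 ± 0.17), AT3G62550 (2.19 ± 0.13), AT1G23390 (2.16 ± 0.15), AT5G48490 (1.98 ± 0.19), AT3G06070 (1.94 ± 0.13), AT5G24210 (1.91 ± 0.31) and AT1G55960 (1.81 ± 0.09), with adjusted p from 6.63e-09 to 0.00304. The largest falls included AT3G15650 (-1.77 ± 0.30), AT2G16890 (-1.69 ± 0.24), AT3G14200 (-1.59 ± 0.13), AT4G34950 (-1.39 ± 0.13), IQD22 (-1.30 ± 0.23), TINY2, a transcription factor of the AP2/ERF type (-1.16 ± 0.11), AT5G62960 (-1.08 ± 0.09) and AT4G32920 (-1.08 ± 0.15), with adjusted p from 8.44e-07 to 0.00127. Of these AT3G15650, AT2G16890 and IQD22 are dim, so that their sizes depend on the offset, for IQD22 with -2.64 at an offset of 1 and -0.63 at 32. Groups did not overlap for 1681 of the called probe sets and for 28.4% of all tested, where chance gives 10%. The count of calls was 1095 without Ws-2 H 3.

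Changes between the genotypes in L and in H, which share no arrays, correlated across probe sets with Pearson's r = 0.628 and Spearman's rho = 0.508. Genes are not independent replicates, and these are descriptions across genes. Residuals of same-numbered arrays of L and H in a genotype all correlated positively, up to 0.368 for ape2 L 2 with ape2 H 2. Such a link could raise this agreement, and without ape2 L 2 Pearson's r was 0.555. Both conditions called 436 probe sets higher in ape2, against 40.3 for independent lists, and 446 lower, against 42.4, while 3 were higher in L and lower in H. Of the 2380 called in either condition, 2218 (93.2%) had the same sign in both. Averaged over both conditions, limma called 3028 probe sets, 1454 higher and 1574 lower. CSLA01 was at -2.24 (adjusted p = 1.6e-07), JMT at -1.48 (3.18e-09), ATG8E, which is dim in Ws-2 H, at 1.61 (3.18e-09), CCL at 1.25 (2.29e-08), AKINBETA1 at 0.91 (9.99e-07) and APL3 at -0.67 (1.01e-05) in this mean. CHLI2 (0.41, 0.00254) and GI (-0.37, 3.68e-04) kept their calls in the mean without each array.

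**Figure D3:**
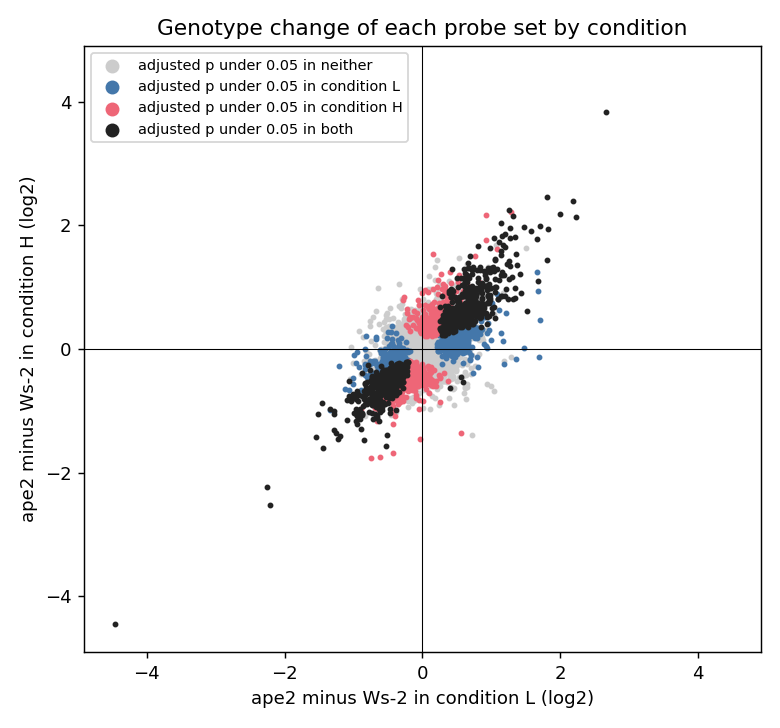
Log2 change of ape2 against Ws-2 in condition L (horizontal) and in condition H (vertical), with 1 point per tested probe set coloured by whether it was called in neither, either or both conditions. The changes correlate with r = 0.628, and CSLA01 lies at -2.25 and -2.23 and ATG8E at 1.27 and 1.95.

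**Figure D4:**
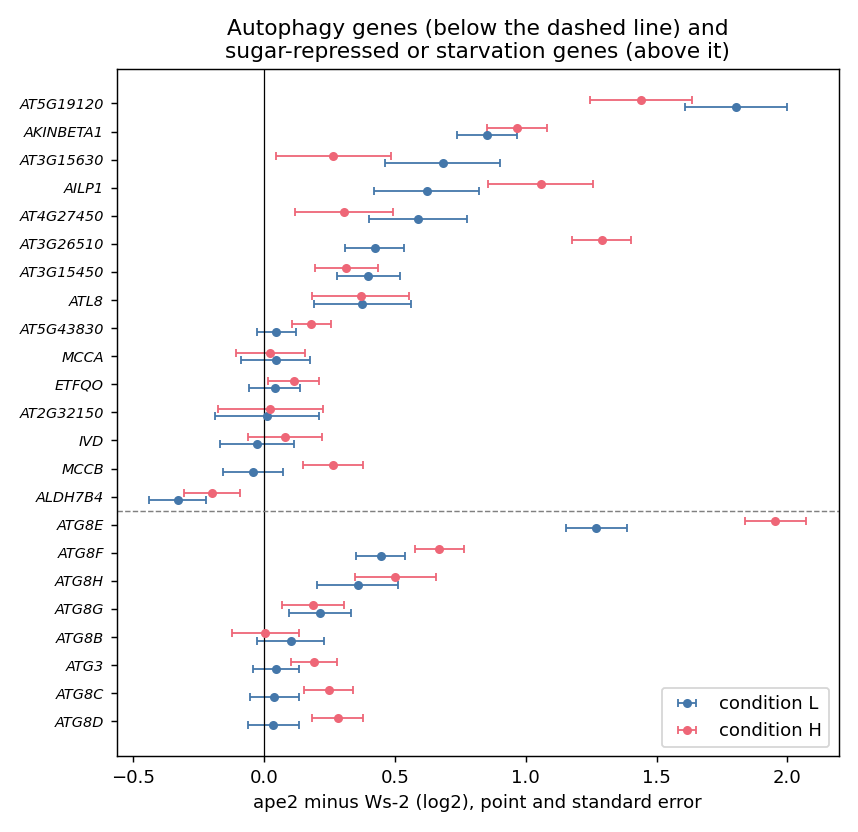
Log2 changes of ape2 against Ws-2 with their standard errors for the measured sugar-repressed and starvation genes and the ATG family, in condition L and in condition H. AT5G19120, which is dim, is at 1.80 and 1.44 and AKINBETA1 at 0.85 and 0.97, while IVD and ETFQO lie between -0.03 and 0.11.

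Condition H was compared with condition L within Ws-2 to describe how the wild type differed between them. The lower 3' to 5' ratios of control genes in H run with condition, and whether RNA integrity contributes to these changes was not tested. CSLA01 rose from a signal of 236 ± 55.8 to 850 ± 62.1 (SD, n = 3), a log2 change of 1.83 ± 0.19 (SE, adjusted p = 2.08e-04), and the sugar transporter gene SAG29 rose from 22.1 ± 2.83 to 95.4 ± 17.5 (1.71 ± 0.23, 8.33e-04). JMT rose by 0.71 ± 0.11 (0.00144) and LHCB4.3, a minor antenna protein of photosystem II, by 0.39 ± 0.06 (0.00307), from 1990 ± 56.9 to 2607 ± 7.02. The cold-regulated genes COR15A and COR15B fell from 2270 ± 352 to 1437 ± 145 (-0.65 ± 0.11, 0.00523) and from 1286 ± 70.0 to 744 ± 84.6 (-0.79 ± 0.10, 5.45e-04). AT5G48490 fell from 189 ± 26.7 to 37.6 ± 11.2 (-2.09 ± 0.19, 6.29e-05).

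Of the 3 cold-response genes measured, 2 fell over all genes tested and 3 were lower when adjusted over the list alone. PORB fell by -0.55 ± 0.07 (adjusted p = 4.01e-04), GH9C2 by -0.57 ± 0.09 (0.00149) and ATG8E, which is dim, by -0.61 ± 0.12 (0.00784, with -0.83 at an offset of 1 and -0.38 at 32). Among 15 sugar-repressed and starvation genes on the extended list 2 fell and 0 rose by limma, with 2 and 0 when adjusted over the list alone, and the camera adjusted p was 0.201. Both are dim. They were AT5G19120 at -0.94 (0.0138), lost without Ws-2 L 2 (0.0728), and ATL8 at -0.76 (0.038), lost without Ws-2 L 1, Ws-2 L 2, Ws-2 L 3, Ws-2 H 1, Ws-2 H 3, ape2 L 1, ape2 L 3 or ape2 H 1 (up to 0.171). The 13 measured plastid-encoded transcripts of the fixed list were lower as a list, with 12 of 13 changes negative, a median of -0.12 and a mean of -0.17 (camera adjusted p = 0.00938, and adjusted p = 0.613 with an estimated correlation). In this list 1 gene passed the test by itself, ndhF at -0.44 (0.0324), and 1 when adjusted over the list alone. Its call was lost without Ws-2 L 1, Ws-2 L 2, Ws-2 L 3, Ws-2 H 1 or Ws-2 H 2 (up to 0.128), and the list's call without Ws-2 L 3, Ws-2 H 2 or Ws-2 H 3 (up to 0.19). Over the 69 measured genes of the plastid genome the mean was -0.16 with 67 negative (camera adjusted p = 3.5e-08, and adjusted p = 0.616 with an estimated correlation). The 8 measured genes of the extended heat shock list had a mean of 0.28 with 0 called singly by limma (camera adjusted p = 0.0371, and adjusted p = 0.616 with an estimated correlation), a call lost with an offset of 1 and without Ws-2 L 1, Ws-2 L 2, Ws-2 H 1 or Ws-2 H 3 (up to 0.158).

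In Ws-2 limma called 474 probe sets, 166 higher and 308 lower in condition H, with 16 rises and 28 falls of at least 2-fold. Further rises were AT3G28270 (1.37 ± 0.14, adjusted p = 5.63e-05), AT3G05400 (0.93 ± 0.17, 0.00515), TBL26 (0.45 ± 0.07, 0.00193) and AT2G27420 (0.53 ± 0.08, 0.0023). Further falls were AT3G62950 (-1.76 ± 0.17), AT1G19960 (-1.47 ± 0.17), AT1G04770 (-1.37 ± 0.21), AT5G60680 (-1.27 ± 0.09), AT5G08520 (-1.22 ± 0.14), AT3G06070 (-1.04 ± 0.13), AT1G23390 (-1.02 ± 0.15), AT3G62550 (-0.90 ± 0.13) and AT1G55960 (-0.51 ± 0.09), with adjusted p from 8.88e-07 to 0.00523. Of these AT3G62950 and AT5G08520 are dim, so that their sizes depend on the offset, for AT3G62950 with -3.72 at an offset of 1 and -0.85 at 32. Groups did not overlap for 473 of the called probe sets and 19.8% of all tested, where chance gives 10%. The count of calls was 315 without Ws-2 L 1, 278 without Ws-2 L 2, 265 without Ws-2 L 3, 284 without Ws-2 H 2 and 270 without Ws-2 H 3, and 305 with a constant prior.

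Within ape2 the same comparison describes how the mutant differed between the conditions, with the same limit. CSLA01 rose from a signal of 41.3 ± 9.97 to 176 ± 42.4 (SD, n = 3), a log2 change of 1.85 ± 0.19 (SE, adjusted p = 1.78e-04), and JMT from 44.7 ± 4.61 to 88.3 ± 13.8 (0.84 ± 0.11, 3.1e-04). APL3 rose by 0.59 ± 0.11 (0.00525) and LHCB4.3 by 0.44 ± 0.06 (0.0011). PORB fell by -0.46 ± 0.07 (0.00141), and EXPA8, an expansin of the cell wall, fell by -1.01 ± 0.13 (3.1e-04). SAG29 rose from 5.23 ± 3.31, close to background, to 51.5 ± 21.2 (1.97 ± 0.23, adjusted p = 2.01e-04), and the size of this change depends on the offset, with 3.17 at an offset of 1 and 1.13 at 32.

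On the extended heat shock list all 8 changes were positive in ape2, AT5G37670, which is dim, rose by 0.90 ± 0.17 (adjusted p = 0.00811), and the mean was 0.38 (camera adjusted p = 0.0123, and adjusted p = 0.261 with an estimated correlation). That list call was lost without ape2 L 1 (0.0855) and with no filter. All 9 measured IQD genes, calmodulin-binding proteins, had negative changes with 0 called singly by limma, and their mean was -0.29 (camera adjusted p = 0.0123, and adjusted p = 0.261 with an estimated correlation), a call lost without ape2 H 2 (0.0845) and with a filter at 50. The GH symbol family had 8 of 8 negative changes and a mean of -0.31 (camera adjusted p = 0.0123, and adjusted p = 0.261 with an estimated correlation), lost without ape2 L 1 (0.0705), with GH9C2 at -0.66 ± 0.09 (3.98e-04). Of 3 cold-response genes 2 fell, and 2 when adjusted over the list alone. They were COR47 at -0.51 (0.0109), lost without ape2 L 1 (0.0571), and COR15B at -0.41 (0.0372), lost without Ws-2 L 1, Ws-2 L 2, ape2 L 1, ape2 L 3, ape2 H 1 or ape2 H 2 (up to 0.145). Of 15 sugar-repressed and starvation genes on the extended list 1 rose and 2 fell, with 3 and 2 when adjusted over the list alone, and the camera adjusted p was 0.828. AT3G26510 rose (0.75 ± 0.11, adjusted p = 0.00131), AT5G19120 fell (-1.31 ± 0.20, 0.00121), and ATL8, which is dim, was at -0.76 (0.0291), lost with an offset of 1 (0.0564) and without ape2 L 1, ape2 L 3, ape2 H 1, ape2 H 2 or ape2 H 3 (up to 0.132). The plastid-encoded list had a mean of 0.06 (camera adjusted p = 0.182).

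In ape2 limma called 648 probe sets, 287 higher and 361 lower in condition H, with 19 rises and 26 falls of at least 2-fold. Further rises were AT3G28270 (1.91 ± 0.14), AT1G57590 (1.06 ± 0.13), AT1G22160 (0.91 ± 0.12), AT3G44970 (0.91 ± 0.13), TBL26 (0.82 ± 0.07), AT4G27652 (0.75 ± 0.14), AT2G27420 (0.74 ± 0.08) and AT1G78020 (0.53 ± 0.07), with adjusted p from 2.42e-06 to 0.00722. Further falls were AT3G62950 (-1.58 ± 0.17), AT5G48490 (-1.58 ± 0.19), AT4G33960 (-1.38 ± 0.20), AT3G06070 (-0.92 ± 0.13), AT5G08520 (-0.86 ± 0.14), AT3G62550 (-0.71 ± 0.13), AT4G34950 (-0.64 ± 0.13) and AT5G60680 (-0.60 ± 0.09), with adjusted p from 7.16e-05 to 0.0102. Groups did not overlap for 647 of the called probe sets and 21.8% of all tested, where chance gives 10%. The count of calls was 367 without ape2 L 1, 402 without ape2 L 3, 373 without ape2 H 3 and 383 when only the ape2 arrays were fitted, and 422 with a constant prior.

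Condition changes in the genotypes, which share no arrays, correlated across probe sets with Pearson's r = 0.398 and Spearman's rho = 0.313. Both genotypes called 74 probe sets higher in H, against 2.96 for independent lists, and 142 lower, against 6.92, and 0 were called in opposite directions by limma. Of 906 called in either genotype, 796 (87.9%) had the same sign in both. The mean of both condition contrasts had 1327 calls, 587 higher and 740 lower. In this mean CSLA01 was at 1.84 (adjusted p = 3.47e-06), AT5G48490 at -1.83 (2.89e-06), COR15B at -0.60 (1.01e-04), COR47 at -0.38 (0.00353) and APL3 at 0.46 (0.00108).

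The interaction asks whether the change from L to H differed between the genotypes. No gene named here was called by limma, with 1229 probe sets at an unadjusted p under 0.05. Of the 3 called probe sets, which were chosen after their values were seen and have no gene named here, 245306_at (0.74 ± 0.10, adjusted p = 0.0179) rose in both genotypes, from 346 to 1499 in Ws-2 and from 172 to 1277 in ape2. Probe set 253971_at (0.82 ± 0.11, 0.0155) went from 757 to 461 in Ws-2 and from 1223 to 1332 in ape2, and 260126_at (-1.01 ± 0.14, 0.0155) from 170.05 to 101.9 and from 255 to 71.9. All of these calls were lost without Ws-2 L 2 or Ws-2 L 3, where limma called 0. The call of 245306_at was also lost without Ws-2 H 3, ape2 L 2 or ape2 H 3 (up to 0.0927), and that of 260126_at without ape2 L 1 or ape2 H 3 (up to 0.0806). The count was 6 without Ws-2 L 1, 7 without Ws-2 H 1, 6 without ape2 H 2, 1 without ape2 H 3, 0 with a constant prior and 10 with array weights. Among named genes with the smallest p, AT3G57450 was at -1.04 (0.0639), AT1G13650 at 0.86 (0.0639), AT3G26510 at 0.87 (0.081) and AT5G60680 at 0.66 (0.081).

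Plastid-encoded transcripts had positive interactions as a list, with a mean change from L to H of -0.17 in Ws-2 and 0.06 in ape2. On the fixed list 12 of 13 were positive with a median of 0.22 and a mean of 0.23 (camera adjusted p = 8.59e-05, and adjusted p = 0.553 with an estimated correlation). Over all genes 0 of the 13 passed by limma, and 2 were higher when adjusted over the list alone. The values of rbcL (0.52, adjusted p = 0.36), ndhF (0.49, 0.413) and petD (0.59, 0.662) did not pass the test. The 69 measured genes of the plastid genome had a mean of 0.22 with 66 positive (camera adjusted p = 1.55e-13, and adjusted p = 0.358 with an estimated correlation). The 5 nuclear photosystem and electron transport subunits had a mean of 0.08 (camera adjusted p = 0.266).

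**Figure D5:**
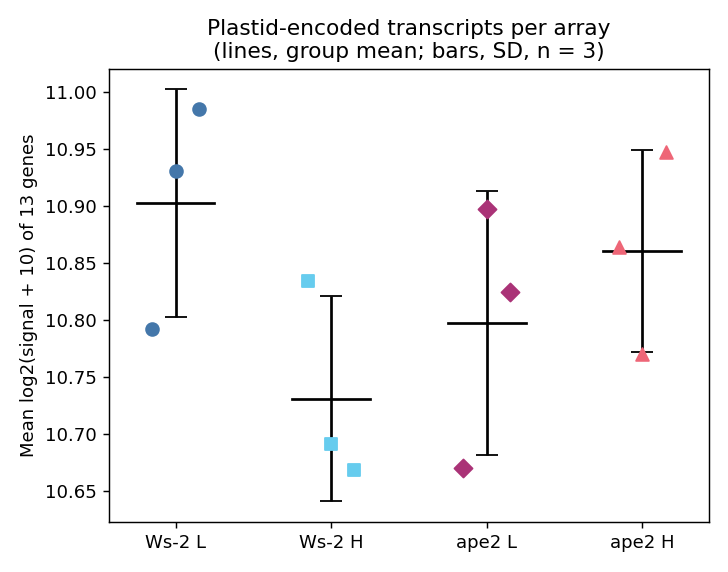
Mean log2 signal of the 13 measured plastid-encoded transcripts on each array (points), by group, with the group mean and SD (n = 3). The difference of H from L is -0.17 in Ws-2 and 0.06 in ape2, an interaction of 0.23.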

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

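Of the tests below, those on matched lists of equal brightness, on transcripts without a poly(A) tail and on the within-group component as the whole cause were chosen after the result was seen. The matched lists were revised after a first result, from the 50 nearest probe sets to the 20 nearest, and both versions led to the same reading. For the plastid list these were drawn from named nuclear genes. For the sugar list they were drawn from all tested probe sets, which include the list's own other members. The test of the within-group component as the whole cause was also replaced after its value was seen. The first test regressed the loading out and was read against that cause and then as deciding nothing, since the correlation of the changes in L and H moved only from 0.628 to 0.625, and the test below uses the fit without 3 arrays.

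The results described here include those where the change from L to H differed between the genotypes in a test of the difference itself. The probe sets 245306_at (0.74), 253971_at (0.82) and 260126_at (-1.01) passed limma, and 12 of 13 plastid-encoded transcripts had positive values with a mean of 0.23. Over the plastid genome the mean was 0.22, with 0.20 for ATP synthase and cytochrome genes, 0.21 for NDH genes, 0.24 for photosystem genes and 0.23 for ribosome and RNA polymerase genes. The call for ATP synthase and cytochrome genes was lost without Ws-2 L 3, Ws-2 H 3, ape2 L 1, ape2 H 1 or ape2 H 3 (camera adjusted p up to 0.169). It was also lost with quantile normalization, and the lowest mean without 1 array was 0.13. The family ATG (0.19) also passed camera, and its call was lost without Ws-2 H 2 or ape2 H 2 (up to 0.0723). The symbol family RPS (0.30) passed as well. It takes in rps genes of the plastid genome, which the plastid lists above already count, so it is not a separate result. With an estimated correlation none of these lists passed, and fry called 0 of them. Residuals put back on other arrays gave as many calls as the real 3 in 2 of 100 orders, the real one included, and 1 other order gave 56 calls, several times the real count, which points to a structure of the samples whose cause was not tested.

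The first pattern is the large number of genes that differ between ape2 and Ws-2. With 3 arrays against 3, the 10 splits are too few to exclude chance: the real counts of 1575 in L and 1690 in H stand against a highest other of 0 and 1, and 1 of 10 splits, the real one, reached each. For the mean over conditions 1 of 100 splits, the real one, gave as many as 3028 calls, with 83 the highest other. That excludes a chance assignment of these arrays by that test. If the replicates are technical, it cannot exclude differences between the plants or harvests behind the groups. The other splits mix the genotypes, which widens the residual spread and lowers their counts. A chromosome segment of another strain as the cause of the whole pattern is argued against, as 0% of called genes lay in windows fuller than reshuffled ones, though a small segment stays open. Variation shared by arrays within groups was examined through its leading component. Without the 3 arrays highest on it 8.79% of its within-group sum of squares was left and the genotype change along it went from 5.35 to -0.887. In that fit 2247 of the 3028 calls kept their direction, so these calls did not rest on those 3 arrays. The fit does not decide whether such variation is the whole cause. The loading correlates with the genotype change at only 0.160, so few calls could be lost with it. The 83 is from splits of all 12 arrays and sets no limit for that fit. As a part of the cause this variation cannot be told apart either. The genotype itself stays open and was not tested apart from growth or harvest, which are not given in the sources used here.

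The second pattern is the positive interaction of plastid-encoded transcripts. In 1 of 100 orders of the residuals, the real one, the mean was as large as 0.235, with 0.223 the highest other, so the margin is narrow. Compression of bright signals as the whole cause is argued against only as far as genes vary independently. Of 10000 lists of nuclear genes of equal brightness, 0 had a mean as high, and the highest reached 0.189. Their genes were drawn singly, without the variation that plastid transcripts share, so their spread may be too narrow. As a part of the cause compression cannot be told apart, with a matched mean of 0.0619. Neither can a varying share of RNA without a poly(A) tail, because the 12 mitochondrial genes had a mean of 0.0637 with a standard error of 0.0593. A response of plastid transcripts that depends on genotype stays open and untested.

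The third pattern is the higher level in ape2 of the extended list of sugar-repressed and starvation genes, drawn up after reading the annotation. The fixed list of such genes holds 22, of which 5 have a probe set named here. For ape2 against Ws-2, camera called 0 of the 7 fixed lists in L, in H or in the mean over both conditions. The mean of the extended list over both conditions was 0.400, reached in 1 of 100 splits, the real one, with 0.336 the highest other. Noise of dim signals that is independent between genes is argued against, since 0 of 10000 lists of equal brightness had a mean as high. The highest of these reached 0.277. Their genes were drawn singly, so variation shared by the genes of the list was not tested. With an estimated correlation the list's camera adjusted p was 0.324. Without the 3 arrays highest on the leading component of variation within groups the mean was 0.381. That fit does not decide whether such variation is the whole cause, since little of the mean lay along the component and could be lost. The 0.336 is from splits of all 12 arrays and sets no limit for that fit. The test of this variation as a part of the cause decided nothing, because the list's loading on that component exceeds that of 92.4% of matched lists. The part of the list's mean that lay along that component was 0.0180, against the mean of 0.400. This argues against the component as the whole cause or as a large share of it. A lower supply of sugar in ape2 stays open as a candidate explanation, but no sugar was measured in the sources used here.

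The condition contrasts were split in the same way. In Ws-2 and in ape2, 1 of 10 splits, the real one, gave as many as 474 and 648 calls, with 0 and 0 the highest other, and 10 splits are too few to exclude chance. For their mean, 1 of 100 splits gave as many as 1327, with 57 the highest other. That excludes a chance assignment of these arrays by that test, with the same limits as for the genotypes.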

How the results depend on the processing

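The fit without the 3 arrays highest on the within-group component was chosen after seeing the data. Among the genes and lists followed through the alternatives, which are a part of all those called, no call reversed its direction. The values of XPT (AT5G17630), which was not called, changed sign, from -0.01 to 0.08 for ape2 in L and from -0.06 to 0.02 for H in ape2 without 1 array. Why the values below moved was not tested.

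Leaving out 1 array moved the calls for ape2 from 1575 to between 1024 and 1604 in L and from 1690 to between 1095 and 1843 in H. For H against L the range was 265 to 506 in Ws-2, from 474, and 367 to 670 in ape2, from 648, and for the interaction 0 to 7, from 3. A constant prior gave 305 in Ws-2, 422 in ape2 and 0 for the interaction, only the groups compared gave 383 in ape2, and for the interaction array weights gave 10 and the fit without the 3 arrays 14. Fitting only the groups compared is the same model for the interaction and the means. With the replicate block the counts were 1475, 1592, 428, 612 and 2 for these contrasts, and the replicate numbers were not taken to pair the arrays, as 3 of 18 same-numbered pairs of residuals correlated over 0.1 (median 0.0272) and 3 of 12 arrays correlated best with one of their own number. Of the 6 such pairs of L with H in a genotype all were positive, from 0.0444 to 0.368, and 3 were over 0.1, so a link within genotypes stays open.

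Of the fixed lists, camera called 0 for ape2 in L, 0 in H, 1 for H in Ws-2, 0 in ape2 and 1 for the interaction. Without 1 array these were 0 to 1, 0 to 2, 0 to 1 and 0 to 3, and 0 to 2 for the mean of H minus L. Without the 3 arrays they were 1 in L, 1 in H, 3 for H in ape2 and 2 for the interaction. With no filter they were 1 in H and 1 for H in ape2. With fry they were 1 in H, 0 for H in Ws-2, 0 for the interaction and 1 for the genotype mean, and with an estimated correlation 0 for H in Ws-2 and 0 for the interaction.

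The correlation of condition changes was 0.308 with no filter and 0.526 with the filter at 50, from 0.398. That of genotype changes was 0.525 and 0.742, from 0.628, and 0.555 to 0.635 without 1 array.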

Other observations

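The test of opposite directions below was chosen after the result was seen.

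Genotype and condition changes were weakly related across genes. The mean genotype and mean condition changes, which are orthogonal in this design, correlated at -0.202 across probe sets (Spearman's rho = -0.0972), and 3 of 100 splits of the arrays between genotypes, the real one included, gave a value as large in size, with 0.215 the highest other. Of 590 probe sets called in both means, 407 (69.0%) went in opposite directions: 222 were higher in ape2 and lower in H, against 66.9 for independent lists, and 185 were the reverse, against 57.5. In the same direction, 146 were lower in both, also above the 72.5 for independent lists, and 37 were higher in both, against 53.1. CSLA01 was at -2.24 for genotype and 1.84 for condition, AT3G62550 at 2.09 and -0.81, and PORB at 0.41 and -0.51. What relates them was not tested.

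Averaged over genotypes, the IQD family was lower in condition H (mean -0.25, camera adjusted p = 0.00501, and adjusted p = 0.253 with an estimated correlation) and the extended heat shock list was higher (0.33, adjusted p = 0.00501, and adjusted p = 0.253 with an estimated correlation).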
